A study of Mus musculus with 6 samples.

How the data were processed

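Bulk RNA-seq was analysed from MB49, a bladder cancer cell line from a male mouse whose Y-positive form was edited here with CRISPR. The labels name 2 groups of 3 libraries each: Y-KO, named as a CRISPR knockout of Y, and Y-Scr, the control made with a non-targeting guide RNA. The guide behind Y-KO is not given in the sources used here: all 6 libraries carry the same protocol texts, of which the one on growth speaks of the control alone and the one on sorting and clones names no group. Per the labels' protocols, transduced cells were sorted on a red fluorescent protein and grown up from single cells, RNA was taken on RNeasy Plus columns, and stranded TruSeq libraries were made from poly-A RNA. The labels put all 6 libraries in batch 1. They call the samples a cell line and also, under tissue, a tumor, and they do not say whether the replicates of a group were separate cultures or separate clones. The p-values therefore measure only the spread between these samples, which may be technical.

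The authors deposited a table of whole-number read counts per gene, 1 column per library, with no normalization. Per the submitters' processing notes, the tools were FastQC 0.12.1, MultiQC 1.13, Trimmomatic 0.39, STAR 2.5.2b, featureCounts 1.5.3 and DESeq2, with the builds GRCm39 and mm39. The deposited gene coordinates were compared with an annotation of GRCm38: of 54409 genes found in both, 53499 (98.3%) had the same chromosome, start and end, so coordinates are given here as GRCm38. The strand setting of the counting is not given in the sources used here, so counts of genes that overlap on opposite strands are uncertain. The same holds for near-identical copies, such as Ifit3 and Ifit3b, the Oas1 genes, the H2 genes and ribosomal protein genes with their pseudogenes, between which reads could have been split. Gene lengths came with the deposited table.

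The table held 54532 genes, and the libraries held between 15698510 and 24633158 counts. A count floor of 3 then stood at 0.122 to 0.191 CPM (counts relative to the library total) per library. Intervals and floors cover counting error only and not the spread between libraries, since the intervals use counts summed over each group. PCR copies were not marked, so the counting error may be larger than they show. A fold against a group at 0 counts was computed against 3 counts over that group and is written "at least". With 1 to 3 counts in a group, the ratio is given with an exact 95% interval. Each pair of replicates differed by more than sampling noise (chi-square per degree of freedom 3.68 to 17.5), so none was a copy of another library's counts. This does not tell repeat libraries of one culture from separate cultures.

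The groups were compared with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr (12907 genes kept), a robust quasi-likelihood fit with group as the only term, and Benjamini-Hochberg adjustment with a threshold of 0.05. Log2 fold changes are Y-KO minus Y-Scr and are given with their standard error (SE). CPM values were computed here from the counts on the TMM-scaled library sizes, as mean ± SD with n = 3. Gene lists with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over 23 lists, and beside that with an estimated correlation and with fry. Of the 30 lists, 23 met that size, and their medians were the same with genes at 0 counts in a group set to their bound. For 3 list symbols, the table carried an older name. The same test was run over 20 chromosomes and over blocks of 50 neighbouring tested genes, where a shifted block also needed a median of at least 0.3 in size.

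The groups, tests, lists, naming rule and other settings to try were fixed before the data were examined. Named genes were all genes of the Y list and their X partners, the 12 largest rises and 12 largest falls past the threshold with a mean of at least 5 CPM and no overlap between groups (predicted genes and pseudogenes left out), up to 4 members per list with the smallest adjusted p, and Cd274, H2-K1, H2-D1 and B2m. Values of some genes that this rule takes are not reported here. Other members are named in the text as examples of a list's direction, chosen after their values were seen.

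Those settings were other scaling factors, DESeq2 1.42.0, limma-voom, no low-count filter, at least 1 CPM in 3 libraries, protein-coding genes only, the replicate number as a block, each library left out in turn, the estimated correlation, fry and blocks of 25 or 100 genes. A fit with each library's trend on gene length and GC content removed (natural splines with 4 degrees of freedom) was added after the data were seen. The edgeR gene test, camera on lists at the preset correlation and the trend removal were tested on simulated counts for this comparison. Genes were drawn independently there, and the other steps were not simulated. Over 12738 simulated genes with 200 changed, 67% of those changed 1.5-fold and 81% of those changed 2-fold were recovered, and 6 unchanged genes were called. Over 12712 simulated genes, 1 list was called in 5 simulations without change, and the trend removal brought a simulated slope of 0.1 per doubling of length down to 0.0051. Cells that were not edited were not analysed here.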

Results

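RNA from MB49 mouse bladder cancer cells was sequenced in 2 groups, CRISPR Y-KO and CRISPR Y-Scr, with 3 libraries each. The Y-Scr libraries held 15907451, 17005652 and 24633158 counts and the Y-KO libraries 18327877, 15698510 and 17343929. Between 17890 and 18601 genes had at least 1 count in a library. The comparison asks which genes differ in expression between the cells labelled Y-KO and their Y-Scr controls.

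Expression of the listed Y genes was lost in every Y-KO library. In the Y-Scr libraries the 15 listed Y genes held 6764, 7126 and 8889 counts, a sum of 410.1 ± 33.7 CPM, and in the Y-KO libraries they held 0, 0 and 0 counts. Ddx3y, an RNA helicase gene (ENSMUSG00000069045, chromosome Y, 1260771 to 1286629, GRCm38), stood at 155 ± 22.4 CPM in Y-Scr and was at least 2643-fold lower in Y-KO. Eif2s3y, which encodes a translation initiation factor subunit, was at least 2248-fold lower, the histone demethylase gene Kdm5d at least 1132-fold and Uty, the Y-linked partner of Kdm6a, at least 1022-fold. Adjusted p-values of these 4 genes lay between 6.6e-18 and 1.1e-10 in edgeR's quasi-likelihood test. The weakly expressed Uba1y (32 counts in Y-Scr) was at least 9.92-fold lower, Usp9y (16 counts) at least 4.96-fold and Zfy1 (4 counts) at least 1.24-fold, and these 3 genes were below the expression filter of the test. Rbmy had 1 count in Y-Scr, and the other 7 listed genes, Zfy2, Sry, Rbm31y, Ssty1, Ssty2, Sly and Srsy, had 0 counts in all 6 libraries.

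Of all 1570 Y genes in the table, 11 had at least 10 counts over the Y-Scr libraries, and 8 of these had 0 counts in Y-KO. The other 3, singled out after their values were seen, lie together at the far end of the chromosome, between 90753057 and 90844040. They are Gm47283 (239 counts in Y-Scr and 64 in Y-KO), Gm21742 (93 and 41) and Mid1-ps1 (20 and 9). Whether their Y-KO counts came from the Y chromosome was not tested. Gm47283 fell by 1.76 ± 0.33 (SE) on the log2 scale (adjusted p = 0.00025, edgeR's quasi-likelihood test), and Gm21742 stood at -1.02 ± 0.48 (adjusted p = 0.0915).

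**Figure D1:**
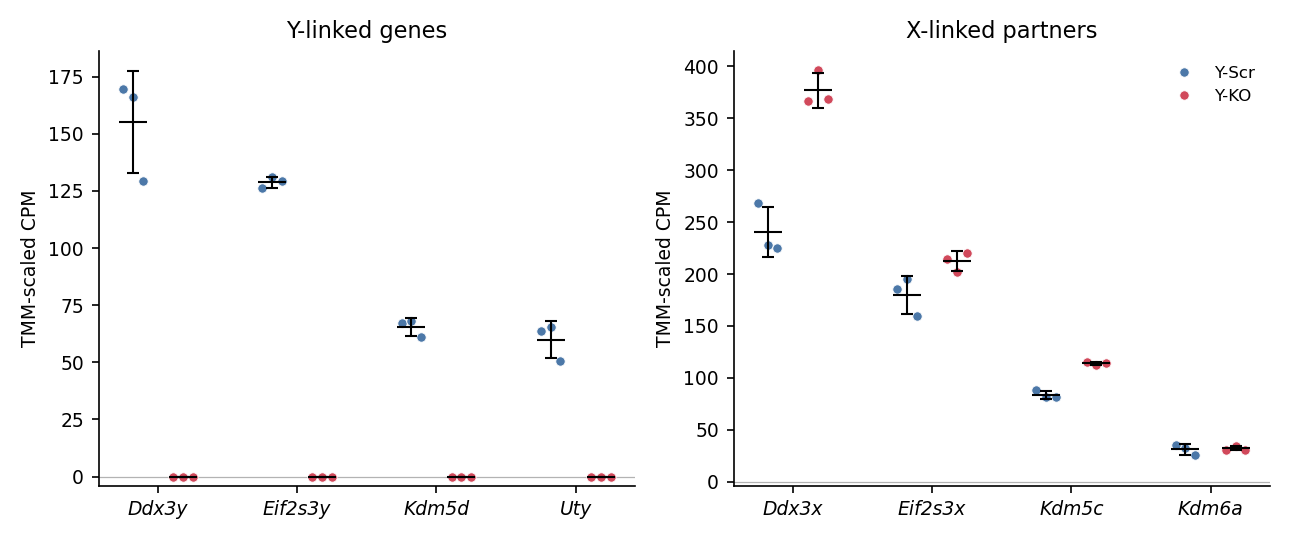
TMM-scaled CPM of 4 Y genes (left) and 4 X-linked partners (right) in each library, with points for libraries, long bars for the mean of 3 and short bars for ± SD. The Y genes stand at 0 in all 3 Y-KO libraries, and Ddx3x rises from 240.4 to 377 CPM.

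The X-linked partners of the lost genes moved unequally. Ddx3x (ENSMUSG00000000787, chromosome X, 13280970 to 13294052) rose by 0.65 ± 0.07 (SE), from 240.4 ± 24.3 to 377 ± 16.8 CPM (adjusted p = 6.5e-07, edgeR's quasi-likelihood test). Kdm5c rose by 0.45 ± 0.06, from 83.7 ± 3.78 to 114 ± 1.7 CPM (adjusted p = 1.9e-05). Eif2s3x (0.24 ± 0.07), Usp9x (0.23 ± 0.09) and Uba1 (0.17 ± 0.06) rose by less. Kdm6a, the partner of Uty, stood at 0.05 ± 0.11, Zfx at -0.10 ± 0.08 and Rbmx at 0.11 ± 0.10, none past the threshold, and Sox3 had 0 counts. In all, 5 of 8 tested partners rose, and 5 when adjusted over the list alone. The list as a set had a median of 0.20 and an adjusted p of 0.0499 with camera, and an adjusted p = 0.326 with an estimated correlation. The set lost its call without Y-Scr 2 (adjusted p = 0.0514), Y-Scr 3 (0.0979) or Y-KO 3 (0.0569), with at least 1 CPM in 3 libraries (0.0521) and among protein-coding genes alone (0.0729). Ddx3x and Kdm5c were past the threshold in every fit run, while 3 partners were called without Y-Scr 2 (Usp9x 0.19 and Uba1 0.16 lost), 4 without Y-Scr 3 (Usp9x 0.15 lost), 3 without Y-KO 1 (Usp9x 0.24 and Uba1 0.16 lost), 3 without Y-KO 2 (Usp9x 0.22 and Uba1 0.18 lost) and 2 without Y-KO 3 (Eif2s3x 0.21, Usp9x 0.22 and Uba1 0.16 lost), and Uba1 (0.16) was also lost with no low-count filter.

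Across the transcriptome, 2667 of 12907 tested genes were higher and 2966 lower in Y-KO at an adjusted p under 0.05. At least 2-fold changes were more frequent among the lower genes, with 561 lower and 175 higher, and without Y-Scr 3 the latter count was 277. The groups did not overlap for 52.9% of tested genes, against 10% by chance for 3 against 3. The first principal component separated the groups and held 85.6% of the variance. The median change of all tested genes was -0.01. Changes also followed gene length and GC content: over 5 equal groups of genes, the median went from -0.14 in the shortest to 0.14 in the longest, and from -0.12 at the lowest GC content to 0.10 at the highest.

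Among genes with a mean of at least 5 CPM that were named by size, the largest rise was that of Piwil2 (ENSMUSG00000033644, chromosome 14, 70372477 to 70429383), a gene of the piRNA pathway of germ cells. It rose by 6.15 ± 0.30 (SE), from 0.193 ± 0.0948 to 13.2 ± 1.72 CPM (adjusted p = 4.2e-12, edgeR's quasi-likelihood test). The X-linked Nxf3, of the mRNA export factor family, rose by 3.53 ± 0.24, Cyp2s1, a cytochrome P450 gene, by 2.80 ± 0.19, and the long non-coding RNA Lncenc1 by 2.62 ± 0.14. Nes, which encodes the intermediate filament protein nestin, rose by 2.05 ± 0.14, and Fgfr3, a growth factor receptor gene often altered in bladder cancer, by 1.32 ± 0.20, from 3.52 ± 0.849 to 8.84 ± 0.449 CPM. Slc9a3r2 (1.75), Cul7 (1.63), Speg (1.61), Tmem37 (1.58), Gpr161 (1.57) and Podnl1 (1.46) made up the rest of the 12 largest rises. After the 4 Y genes, the largest fall among genes at that level was that of Pthlh, which encodes parathyroid hormone-related protein, with 947 counts in Y-Scr and 1 in Y-KO, a ratio of 881 (exact 95% interval 158 to 34826). The other 7 were Rtp4, Ifit1, Oasl2, Csf2, Isg15, Ifi44 and Oas2. Rtp4 fell from 1707 counts to 3, a ratio of 529 (exact 95% interval 181 to 2569).

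Interferon-stimulated genes fell together. Of 29 tested genes of the interferon response list, 28 fell and 0 rose, the same counts as when adjusted over the list alone, with a median of -4.23. Isg15, a ubiquitin-like protein gene (chromosome 4, 156199424 to 156200818), fell by 7.50 ± 0.22 (SE), from 35.9 ± 4.72 to 0.191 ± 0.0330 CPM (adjusted p = 1.3e-15, edgeR's quasi-likelihood test). Usp18, which encodes a negative regulator of interferon signalling, fell by 6.67 ± 0.20 and the antiviral gene Rsad2 by 5.51 ± 0.15. The transcription factor genes Irf7 (-5.33), Irf9 (-3.08) and Stat2 (-1.43) were also lower. Ifit2 was the exception, at 0.13 ± 0.10 (adjusted p = 0.312), with a mean of 27.0 CPM in Y-Scr and 29.5 in Y-KO. The camera test gave an adjusted p of 1.1e-89, and 0.0016 with an estimated correlation. The nucleic acid sensing list holds sensors and also other genes of their pathways, such as Irf3 and Tbk1. Of its 9 tested genes, 5 fell and 1 rose, also when adjusted over the list alone. Its median was -0.28, or -0.15 with the trend on length and GC content removed, with an adjusted p of 0.00016 with camera. Ifi203 fell by 4.23 ± 0.20, Ifi204 by 2.81 ± 0.11 and Aim2, a DNA sensor gene, by 0.67 ± 0.07. Mavs, which encodes the adaptor of RNA sensors, rose by 0.46 ± 0.08.

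Cytokine and chemokine genes were lower as well. Of 24 tested, 19 fell and 0 rose over all genes, and 20 fell and 1 rose when adjusted over the list alone, with a median of -1.66 (adjusted p = 2.6e-54, camera). Csf2, which encodes the growth factor GM-CSF (ENSMUSG00000018916, chromosome 11, 54247271 to 54249667), fell by 7.66 ± 0.15 (SE), from 129 ± 12.96 to 0.624 ± 0.211 CPM (adjusted p = 6.6e-18, edgeR's quasi-likelihood test). The neutrophil-attracting chemokine genes Cxcl1 and Cxcl2 fell by 3.52 ± 0.08 and 3.56 ± 0.07, from 669 ± 63.9 to 58.2 ± 4.62 CPM and from 612 ± 32.2 to 52.0 ± 1.74 CPM. Cxcl10, a chemokine gene induced by interferon, fell by 4.17 ± 0.09, and Ccl20 (-5.45) and Il6 (-4.33) were lower too. Targets of the transcription factor NF-kB followed: 16 of 18 tested fell and 0 rose, also when adjusted over the list alone, with a median of -1.43 (adjusted p = 1.3e-42, camera). Tnfaip3, which encodes an inhibitor of NF-kB signalling, fell by 3.21 ± 0.10, the adhesion molecule gene Vcam1 by 2.92 ± 0.11, the complement gene C3 by 2.04 ± 0.08 and Nfkbiz by 1.67 ± 0.07.

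**Figure D2:**
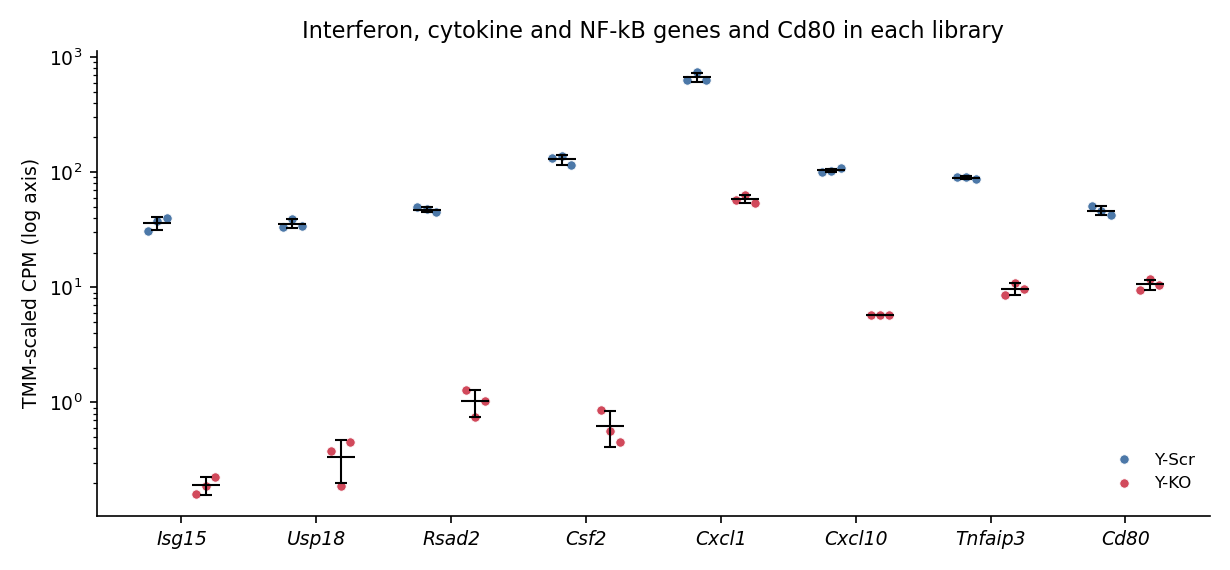
TMM-scaled CPM on a log axis of 8 genes in each library, with points for libraries, long bars for the mean of 3 and short bars for ± SD. All Y-KO libraries lie below all Y-Scr libraries for each gene, with Isg15 at 35.9 against 0.191 CPM and Cxcl1 at 669 against 58.2 CPM.

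Genes of antigen presentation on MHC class I were lower, by less than the interferon list. Of 17 tested, 13 fell and 1, the chaperone gene Canx (0.36), rose, also when adjusted over the list alone, with a median of -0.54. B2m, the light chain shared by class I molecules, fell by 0.74 ± 0.06 (SE), from 475 ± 18.5 to 284 ± 6.27 CPM (adjusted p = 1.1e-08, edgeR's quasi-likelihood test). H2-D1 fell by 0.54 ± 0.06, H2-T23 by 1.01 ± 0.07, the peptide transporter gene Tap1 by 1.16 ± 0.10. Nlrc5, which encodes an activator of class I genes, fell by 1.62 ± 0.17. H2-K1 fell by 0.18 ± 0.07 (adjusted p = 0.0299) and lost that call without Y-Scr 3 (-0.12), Y-KO 1 (-0.20), Y-KO 2 (-0.15) or Y-KO 3 (-0.19) and with the trend on length and GC content removed (-0.11). The list had an adjusted p of 9.0e-06 with camera, and an adjusted p = 0.0979 with an estimated correlation. Of the 7 MHC class II genes, 3 were tested: Cd74 fell by 1.33 ± 0.10, H2-DMb1 fell by 1.65 ± 0.29, and H2-DMa stood at -0.27 ± 0.54.

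Of 8 tested ligands of immune checkpoints, 6 fell and 0 rose, also when adjusted over the list alone, with a median of -0.75 (adjusted p = 1.3e-06, camera). Cd274, which encodes PD-L1 (ENSMUSG00000016496, chromosome 19, 29367455 to 29388095), fell by 1.05 ± 0.17 (SE), from 8.92 ± 0.662 to 4.33 ± 0.521 CPM (adjusted p = 7.9e-05, edgeR's quasi-likelihood test). The T cell co-stimulation gene Cd80 fell by 2.13 ± 0.11, the poliovirus receptor gene Pvr by 1.14 ± 0.06, Cd47, whose product restrains phagocytosis, by 0.79 ± 0.06 and Lgals9 by 0.71 ± 0.08.

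The list of immediate early and stress genes was lower as a set. Of 21 tested, 13 fell and 4 rose, also when adjusted over the list alone, with a median of -0.76 (adjusted p = 3.8e-10, camera). Dusp1, a phosphatase gene, fell by 1.87 ± 0.10 (SE), and Ier2 fell by 1.34 ± 0.07. The transcription factor gene Junb fell by 1.71 ± 0.06 and Klf6 fell by 1.23 ± 0.07. The 4 that rose were Hsph1 (0.78), Hspa1b (0.54), Hsp90aa1 (0.35) and Hspa8 (0.28), which encode heat shock proteins, while Dnajb1, which encodes another, stood at 0.04 ± 0.07. In the list of Wnt, Notch and Hippo targets, 5 of 9 tested fell and 2 rose, also when adjusted over the list alone, with a median of -0.49, or 0.08 with no low-count filter (adjusted p = 0.0016 with camera, and adjusted p = 0.0572 with an estimated correlation). Cyr61 and Ankrd1, both known targets of the Hippo pathway, fell by 1.96 ± 0.07 and 1.14 ± 0.06, Hes1 by 0.86 ± 0.13 and Jag1 by 0.66 ± 0.07. Notch1 (0.91) and the Wnt target Axin2 (2.68) rose. In the basal and squamous list, 3 of 9 tested fell and 0 rose, also when adjusted over the list alone, with a median of -0.03 and a mean of -0.54 (adjusted p = 0.0037 with camera, and adjusted p = 0.0673 with an estimated correlation). Lamb3 (-1.57 ± 0.08), which encodes a chain of the basement membrane protein laminin, and Cd44 (-0.49 ± 0.06) were among those that fell, while the keratin genes Krt14 (0.08 ± 0.22) and Krt16 (-0.51 ± 0.31) did not pass. The list median was -0.27 without Y-Scr 1, -0.05 without Y-Scr 2, -0.07 without Y-Scr 3, -0.25 without Y-KO 1, -0.21 without Y-KO 2, -0.27 without Y-KO 3, -0.24 with no low-count filter and -0.16 with the trend on length and GC content removed. Itgb4 stood at 0.17 ± 0.07 (adjusted p = 0.0509) and was called without Y-Scr 1 (0.22) or Y-KO 1 (0.22) and with other scaling factors (0.18 in both), at least 1 CPM (0.17) or protein-coding genes alone (0.16).

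Genes of lipid synthesis and cell division were modestly higher. In the cholesterol and fatty acid list, 17 of 28 rose and 1, Msmo1 (-0.36), fell, also when adjusted over the list alone, with a median of 0.28 (adjusted p = 1.8e-06, camera). Acaca, which encodes the enzyme of the committed step of fatty acid synthesis, rose by 0.91 ± 0.07 (SE), the desaturase gene Scd2 by 0.89 ± 0.07, and the sterol reductase gene Dhcr7 by 0.61 ± 0.07. Of 28 mitosis genes, 16 rose and 0 fell, 17 when adjusted over the list alone, with a median of 0.22 (adjusted p = 8.1e-05, camera). Cenpf rose by 0.68 ± 0.09, Bub1b by 0.59 ± 0.07, Plk1 by 0.56 ± 0.06 and Tpx2 by 0.47 ± 0.06, all with known roles on the spindle or kinetochore. Of 28 DNA replication genes, 17 rose and 1, Prim1 (-0.41), fell, and 18 rose and 3 fell when adjusted over the list alone, with a median of 0.22 (adjusted p = 0.00093, camera). Chaf1a, a histone chaperone gene, rose by 0.79 ± 0.09, Cdc6 by 0.68 ± 0.09, Uhrf1 by 0.63 ± 0.06 and the helicase gene Mcm4 by 0.56 ± 0.06.

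Ribosomal protein genes were slightly lower: 20 of 35 fell and 0 rose, 21 when adjusted over the list alone, with a median of -0.22 (adjusted p = 0.0065 with camera, and adjusted p = 0.650 with an estimated correlation). Rps16 fell by 0.74 ± 0.09 (SE), Rpl5 by 0.45 ± 0.06, Rps14 by 0.45 ± 0.06 and Rpl3 by 0.42 ± 0.06. This list's call was lost without Y-Scr 3 (adjusted p = 0.0979), by fry (0.0524) and with the trend on length and GC content removed (0.126). The calls of the interferon response, nucleic acid sensing, cytokine, NF-kB, checkpoint ligand, immediate early, cholesterol and fatty acid, mitosis and DNA replication lists held with an estimated correlation, at adjusted p-values between 0.0016 and 0.0477.

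The other 9 tested lists did not pass camera. By fry, which does not compare a list with other genes, the collagen (adjusted p = 0.0364) and histone demethylase (0.0216) lists passed as higher. The mesenchymal (0.00073), p53 (0.00065) and unfolded protein (0.0040) lists passed fry as lower. In the collagen and matrix list 10 of 23 rose and 3 fell, and 11 rose and 3 fell when adjusted over the list alone (median 0.25, adjusted p = 0.0511, camera). It passed without Y-Scr 1 (0.0290), Y-KO 1 (0.0379) or Y-KO 3 (0.0302), with upper-quartile scaling (0.0495), with no low-count filter (0.0487) and with at least 1 CPM (0.0468), while with the trend on length and GC content removed the median was 0.10 (0.463) and without Y-Scr 2 it was 0.15 (0.0791). Col6a2 rose by 1.09 ± 0.10 (SE), Col6a1 by 0.90 ± 0.08 and Col4a1 by 0.57 ± 0.06, while the collagenase gene Mmp13 fell by 3.70 ± 0.26. Of 16 tested histone demethylase genes outside the X and Y lists, 6 rose and 0 fell, also when adjusted over the list alone (median 0.12, adjusted p = 0.110; 0.07 without Y-Scr 3 and 0.01 with the trend on length and GC content removed), among them Kdm4b (0.56 ± 0.11), Kdm2b (0.48 ± 0.08), Kdm2a (0.39 ± 0.07) and Jmjd6 (0.30 ± 0.07). Of 11 mesenchymal genes, 2 rose and 4 fell over all genes and when adjusted over the list alone: Snai1 and Axl rose by 2.66 ± 0.46 and 0.25 ± 0.06, and Snai2 (-1.03 ± 0.09) was among those that fell. Its median (0.09) and mean (0.03) lay above 0, while camera ranked it lower (adjusted p = 0.474) and the median with the trend on length and GC content removed was -0.11. Without Y-Scr 1 that median was 0.06, without Y-KO 1 it was 0.03 and without Y-KO 2 it was 0.03. Of 9 luminal genes, 4 rose and 3 fell, and 5 rose and 3 fell when adjusted over the list alone (median 0.34, or 0.21 with that trend removed, adjusted p = 0.435). The keratin genes Krt19 and Krt8 rose by 2.37 ± 0.23 and 0.36 ± 0.06, and the transcription factor genes Gata3 and Elf3 fell by 1.48 ± 0.21 and 1.14 ± 0.16.

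Of 19 p53 targets, 5 rose and 8 fell, also when adjusted over the list alone, with a median of -0.02, a mean of 0.13 and a lower direction in camera (adjusted p = 0.154, and 0.0487 with no low-count filter, where it passed). Its median was -0.04 without Y-Scr 1, -0.04 without Y-Scr 2, -0.03 without Y-Scr 3, -0.07 without Y-KO 1 and -0.01 without Y-KO 2. Fas fell by 2.43 ± 0.13 (SE), Plk2 by 1.37 ± 0.06 and Btg2 by 1.23 ± 0.11, and Perp, at 0 counts in Y-Scr and 82 in Y-KO, was at least 29.4-fold higher. Of 22 genes of the unfolded protein and amino acid stress list, 5 rose and 8 fell, and 6 rose and 8 fell when adjusted over the list alone, with a median of -0.01, or 0.06 with the trend on length and GC content removed, 0.01 without Y-KO 2, -0.04 without Y-Scr 1, -0.04 without Y-KO 1, -0.01 without Y-Scr 2 and -0.01 without Y-KO 3 (adjusted p = 0.228, camera). Ddit3, a transcription factor gene induced by stress, fell by 1.21 ± 0.07, Trib3 by 0.72 ± 0.06, Asns by 0.49 ± 0.06 and Herpud1 by 0.49 ± 0.06. In the glycolysis and hypoxia list 7 of 30 entries rose and 8 fell, also when adjusted over the list alone, with Aldoa standing for 2 entries, a median of 0.06 (0.08 without Y-KO 2), a mean of -0.01 and a higher direction in camera (adjusted p = 0.555). Pfkfb3 fell by 1.70 ± 0.12, Car9 by 0.71 ± 0.09 and Ndrg1 by 0.59 ± 0.07, and Adm rose by 1.03 ± 0.10. Of 33 nuclear genes of oxidative phosphorylation, 2 rose and 13 fell, also when adjusted over the list alone (median -0.09, adjusted p = 0.228, lower in camera but higher with the trend on length and GC content removed, at a median of -0.02; -0.14 without Y-Scr 1 and -0.06 without Y-KO 2), with Ndufb9 at -0.48 ± 0.09, Cox4i1 at -0.36 ± 0.06, Ndufa9 at -0.33 ± 0.07 (a call lost with that trend removed, -0.13) and Sdha at 0.35 ± 0.06. Of 12 mitochondrially encoded genes, mt-Co3 (-0.52 ± 0.17, adjusted p = 0.0190) passed over all genes and 0 when adjusted over the list alone, with a list median of -0.24, or 0.13 with the trend on length and GC content removed (adjusted p = 0.535, camera). That list passed without Y-KO 2 (median -0.39, adjusted p = 0.0360), its median was -0.12 without Y-KO 3, and mt-Co3 lost its call without Y-Scr 1 (-0.47) or Y-KO 3 (-0.32) and with that trend removed (-0.16). mt-Co1 stood at -0.35 ± 0.13 and mt-Nd4 at -0.34 ± 0.15, both called without Y-KO 2 (-0.50 and -0.51), with no low-count filter (-0.36 and -0.35) and by limma-voom (-0.36 and -0.36), and mt-Co1 also with upper-quartile scaling (-0.34) and protein-coding genes alone (-0.36). mt-Nd3 stood at 1.09 ± 0.48 on 25 and 49 counts, and was called with the trend removed (1.47).

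**Figure D3:**
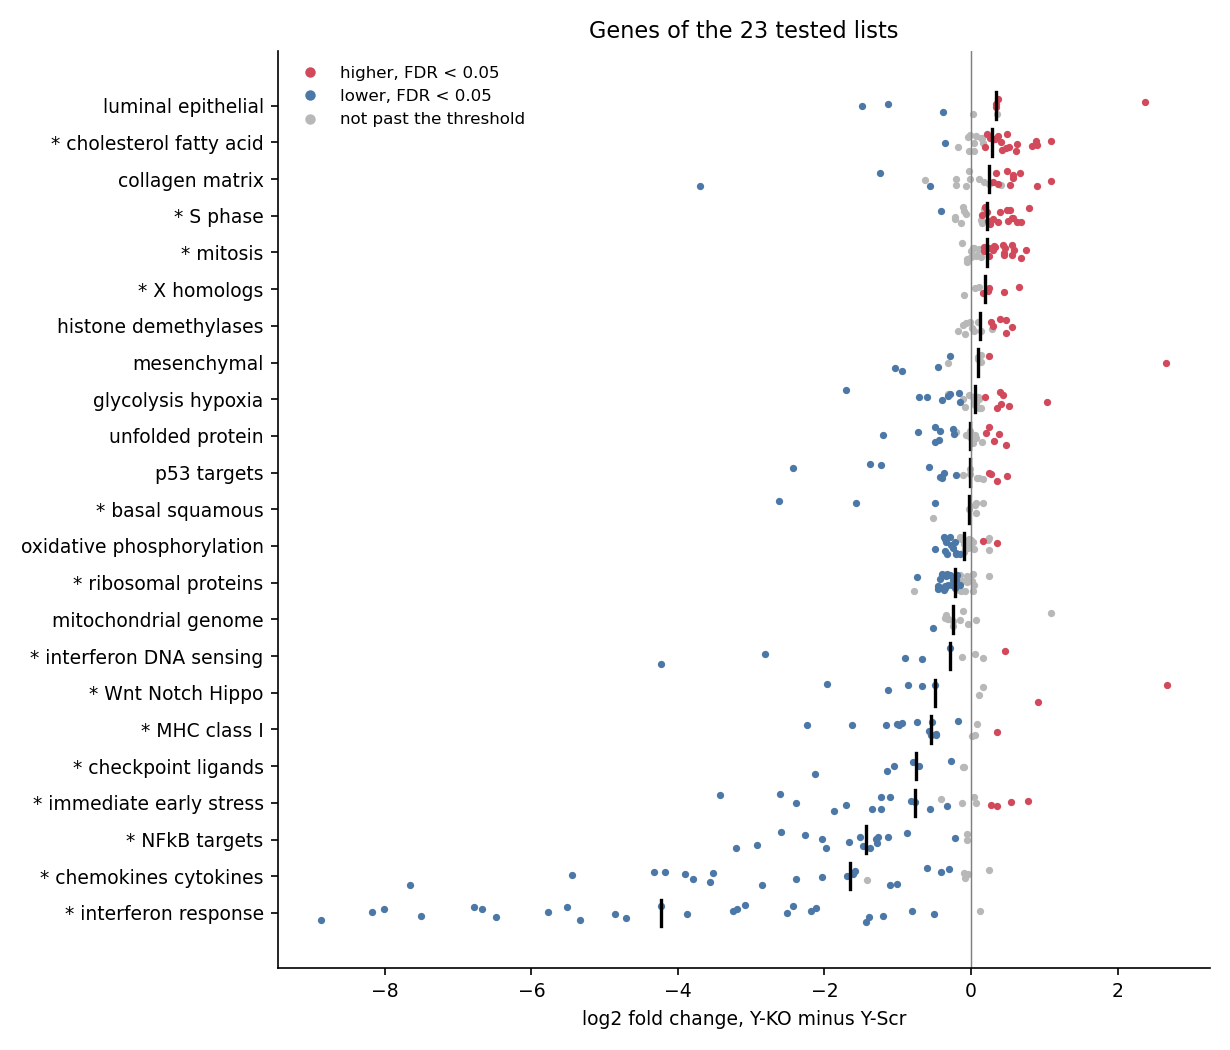
Log2 fold change (Y-KO minus Y-Scr) of each tested gene in the 23 lists, coloured by the test of single genes, with a black bar at the list median and a star where camera passed at 0.05. Ifit3b, Zbp1 and Perp, at 0 counts in a group, and the weaker Aldoa entry are not drawn, and the medians run from -4.23 (interferon response) to 0.34 (luminal).

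Markers of other cell types were mostly near the floor. Of 27 leukocyte genes, 24 lay under 1 CPM in both groups, and the list summed to 169 ± 1.99 CPM in Y-Scr and 138 ± 4.0 in Y-KO, most of it from Cd68 (110 ± 4.03 and 97.6 ± 2.62 CPM). Cd14 fell by 0.56 ± 0.08 (SE), Lyz2 stood at -0.56 ± 0.42, and Cd68 fell by 0.17 ± 0.06 (adjusted p = 0.0357, edgeR's quasi-likelihood test) but lost that call without Y-Scr 3 (-0.14), Y-KO 1 (-0.17), Y-KO 2 (-0.15) or Y-KO 3 (-0.19), with upper-quartile scaling (-0.16), no low-count filter (-0.18), DESeq2 (-0.16) and the trend on length and GC content removed (-0.03). The 11 endothelial genes summed to 5.15 ± 0.571 CPM in Y-Scr and 3.501 ± 0.58 in Y-KO, with Flt1 at -0.99 ± 0.33, a call lost without Y-Scr 2 (-0.83), Y-Scr 3 (-0.91) or Y-KO 3 (-0.81) and by DESeq2 (-0.98), and Esam at -0.68 ± 0.38. The 11 fibroblast and mural genes summed to 12.5 ± 1.09 and 18.3 ± 1.14 CPM, with Pdgfra higher by 0.73 ± 0.13, Dcn at 0.25 ± 0.31 and Des at -0.40 ± 0.48. The 6 erythroid genes summed to 0.348 ± 0.2 and 0.428 ± 0.365 CPM. The 7 MHC class II genes summed to 37.5 ± 0.887 and 15.3 ± 0.599 CPM, and the 19 germline genes to 38.8 ± 2.33 and 26.0 ± 1.79 CPM, where Rhox5 fell by 0.85 ± 0.17 and Xlr3a by 0.46 ± 0.11.

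No whole chromosome was shifted. Chromosome medians lay between -0.08 and 0.04, and camera called 0 of 20 chromosomes, also 0 at an unadjusted p under 0.05. With an estimated correlation camera called 0 after adjustment, and the lowest unadjusted p was 0.0323, for chromosome 6. The 395 tested genes of the X chromosome had a median of -0.01 (95% interval -0.06 to 0.03). Of 246 blocks of 50 neighbouring genes, 2 passed camera, 25 had an unadjusted p under 0.05, and 0 met both the threshold and the median of 0.3. Those 2 were a block of chromosome 5 (86109287 to 95862715), which holds the Cxcl1, Cxcl2, Cxcl10 and Cxcl11 chemokine genes, with a median of -0.295, and a block of chromosome 1 (171113918 to 175913489) with Ifi203, Ifi204, Ifi205 and Ifi207, with a median of -0.26. Without Y-Scr 1, Y-Scr 2 or Y-KO 1 there was 1 block that met both conditions, without Y-Scr 3 there were 3, and without Y-KO 2 or Y-KO 3 there were 0.

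**Figure D4:**
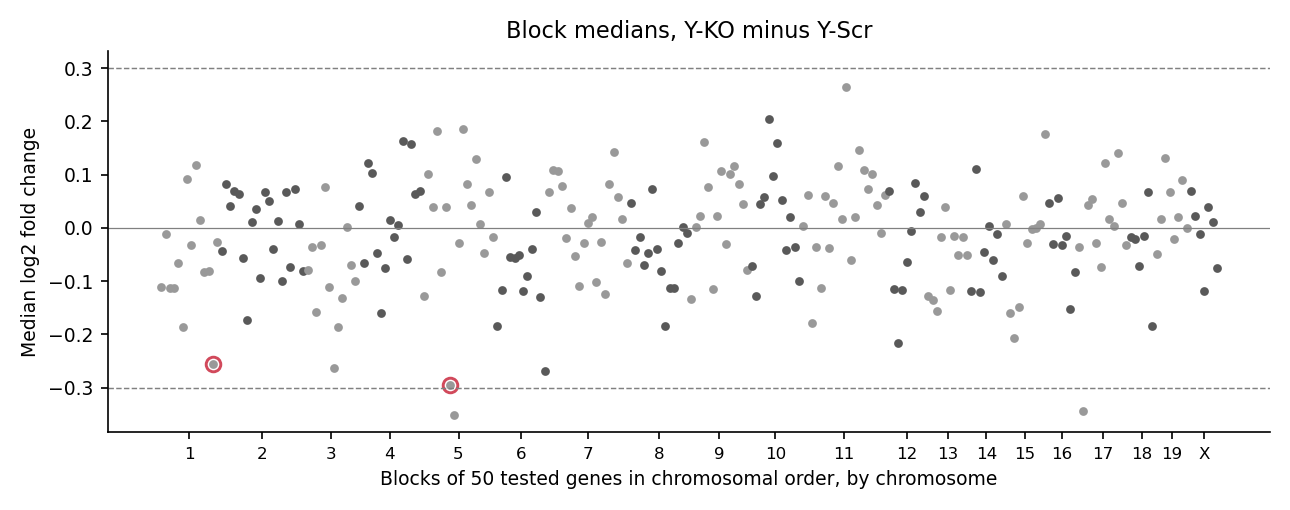
Median log2 fold change (Y-KO minus Y-Scr) of each block of 50 tested genes in chromosomal order, in alternating shades by chromosome, with red rings around the 2 blocks past camera's threshold and dashed lines at 0.3 and -0.3. The medians run from -0.35 to 0.27.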

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

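The fit with the length and GC trend removed was chosen after the data were seen, and all other settings were planned. The counts of higher and lower genes, over all and at least 2-fold, and the 0 shifted chromosomes stayed within 1.5 times under every setting other than the left-out libraries. In each setting, no named gene past the threshold there or in the reported fit changed direction. Of the 5633 genes called, 96.6% were also called by limma-voom, 88.6% by DESeq2 and 79.3% with the trend removed. With each library left out, higher genes ranged from 2141 to 2803, lower genes from 2458 to 3000, at least 2-fold higher genes from 158 to 277, and X partners called from 2 to 5. Of 133 named genes, 126 to 132 kept their side of the threshold in each setting (130 of 131 with the filter at 1 CPM, 130 of 132 among protein-coding genes). With an estimated correlation, 6 lists were lower, not 10, and 3 higher, not 4; fry called 12 lower and 6 higher. Shifted blocks, 0 as reported, numbered 4 with no low-count filter, 2 with at least 1 CPM, 2 among protein-coding genes, 7 at 25 genes, 1 at 100 genes, and 0 to 3 with a library left out. Overlapping blocks of chromosome 3, starting between 94760069 and 95760341, recurred. Their median was -0.42 with no low-count filter, with at least 1 CPM and among protein-coding genes. It was -0.34, -0.37 and -0.34 without Y-Scr 1, 2 or 3. With a Y-KO library left out, none lay on chromosome 3. Blocks of chromosome 5 with Cxcl1 and Cxcl2 also recurred, at -0.37, -0.34 and -0.33 under those gene filters in turn. The cause was not tested. Of the lists, camera turned from lower to higher for the mitochondrial genome and oxidative phosphorylation lists with the trend removed, neither past the threshold. No block was shifted in the reported fit, so the lists without genes of shifted blocks gave no value.

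The replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at -0.35, -0.22 and -0.07. With the number as a replicate block, 2333 genes were higher and 2627 lower, 168 and 553 at least 2-fold, 4 X partners (without Uba1) and 3 lists were higher, 10 lists were lower, and the X partner list had an adjusted p of 0.0585. Depth limits genes near the floor of 3 counts, such as Usp9y and Zfy1.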

Other observations

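Genes described next were chosen after their values were seen. Ifnb1, the interferon beta gene, had 22, 30 and 48 counts in the Y-Scr libraries and 0 in each Y-KO library, at least 31.0-fold lower. Ddx58, which encodes the RNA sensor RIG-I, fell by 1.88 ± 0.10 (SE), the NF-kB subunit gene Rela by 0.96 ± 0.06 and the interferon gamma receptor gene Ifngr1 by 0.89 ± 0.08. The kinase genes Jak1 and Tyk2, whose products bind the type I interferon receptor, rose by 0.27 ± 0.07 and 0.33 ± 0.09, and the receptor genes Ifnar1 (0.12 ± 0.08) and Ifnar2 (-0.26 ± 0.11, adjusted p = 0.0529, edgeR's quasi-likelihood test) did not pass. The growth factor genes Ereg and Hbegf, ligands of the EGF receptor, fell by 1.51 ± 0.08 and 0.98 ± 0.06, and Txnip, which encodes a thioredoxin inhibitor, by 2.33 ± 0.07. Bin2 rose by 6.01 ± 0.44 to 6.12 CPM, Nckap1l by 2.86 ± 0.27 to 5.89 CPM and Spn by 1.23 ± 0.13. Members of the MAGE family moved apart: Magea3 was at least 21.1-fold higher, while Magea8 fell by 4.17 ± 0.40 and Mageb2 fell by 4.22 ± 0.43. Irs1, the insulin receptor substrate gene, was at least 45.9-fold higher.

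A scan of 186 symbol families of at least 8 tested genes, also run after the main results, found 12 of 12 Ifi genes lower (median -3.29, adjusted p = 0.0573 with an estimated correlation), 9 of 11 Serpinb genes lower (median -0.87), 16 of 27 Kif genes, which encode kinesin motors, higher with 2 lower (median 0.28), and 12 of 20 Nup genes, which encode nucleoporins, higher with 1 lower (median 0.22). These families passed camera at adjusted p-values of 1.1e-28, 0.0040, 0.0094 and 0.0318, as did the Ccl (7 of 8 lower), Cd (15 of 30 lower and 2 higher), Irf (4 of 10 lower and 4 higher), Parp (7 of 12 lower and 1 higher) and Ly (5 of 10 lower) families, at 1.2e-18, 0.0027, 0.0033, 0.0111 and 0.0299. The Ly family did not pass with the length and GC trend removed (0.0952). With an estimated correlation 0 of the 186 passed. Outside the blocks named in the report, 3 blocks had adjusted p-values just above the threshold: chromosome 3, 94443318 to 96171718 (median -0.26, 0.0541), chromosome 6, 136506167 to 149563329, which holds Pthlh (median -0.27, 0.0559), and chromosome 11, 76726602 to 79623163 (median 0.27, 0.0587). In blocks of 25 genes each of the 3 regions held a block past both conditions, with medians of -0.42 on chromosome 3, -0.53 on chromosome 6 and 0.35 on chromosome 11. The lowest genes of the one on chromosome 3 were Golph3l (-1.22), Ensa (-1.11) and Mcl1 (-1.01), and the next block along, which holds Txnip, had a median of -0.44.

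Tests on white blood cells, on differences between clones and on an extra X copy were chosen after the results were seen, as was the removal of the length and GC trend, whose outcomes were predicted before that fit was read. The interferon, NF-kB and cytokine lists were lower in Y-KO by medians of -4.23, -1.43 and -1.66. White blood cells in the Y-Scr libraries are argued against by 8 leukocyte genes, Ptprc, Tyrobp, Fcer1g, Laptm5, Csf1r, Itgam, Cd3e and Cd79a. These genes summed to at most 0.380 CPM in a Y-Scr library and up to 0.967 CPM in a Y-KO library. Cxcl1 stood at 669 CPM in Y-Scr. The highest leukocyte-list genes, Cd68 (110 CPM in Y-Scr) and Cd14 (57.4 CPM), were also present in Y-KO (97.6 and 39.0 CPM). A length and GC trend is argued against too, by its size. Over 5 equal groups of genes, medians ran only from -0.14 to 0.14 by length and from -0.12 to 0.10 by GC content. With the trend removed the interferon list kept a median of -4.18, which removing a trend of that size could hardly have changed. What stays open includes a difference between single-cell clones other than the Y chromosome. The labels name 0 clones, so group and clone cannot be told apart for these genes. The Y knockout itself, the difference the design names, was not tested apart from clone. Any other difference that goes with group, such as one between cultures, was not tested either.

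Smaller shifts of whole lists may partly come from a trend of fold change on gene length and GC content (Spearman 0.231 and 0.173 across genes, which are not independent replicates). With that trend removed, the DNA replication list had a median of 0.22 (0.2185), the mitosis list 0.29 (0.2856) and the cholesterol and fatty acid list 0.27 (0.2729), all still past the threshold, which argues against the trend as their whole source. The ribosomal protein list went from a median of -0.22 (quartiles -0.36 to -0.10) to -0.10 (quartiles -0.27 to 0.03), with 13 genes lower and 1 higher, and its call ended because the effect shrank. Its genes are short, with a median length of 1972 against 4000 bases over all tested genes, so the length and GC trend is a candidate explanation for that list. Whether the trend itself arose in the cells or in the libraries stays open.

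The 5 X-linked partners that rose may share a source, and 2 were tested. The length and GC trend is argued against as their whole source, as 5 of 5 stayed called with it removed. Ddx3x went from 0.65 to 0.78 and Eif2s3x from 0.24 to 0.39. Kdm5c shrank from 0.45 to 0.30, Usp9x from 0.23 to 0.17 and Uba1 from 0.17 to 0.13, so part of those rises may follow the trend. An extra copy of the whole X chromosome is argued against by the median of all 395 tested X genes, -0.0088 (95% interval -0.06 to 0.03). A response to the lost expression of the Y-linked partners is a hypothesis that fits the rise of Ddx3x and Kdm5c but was not tested. Kdm6a (0.05 ± 0.11) did not pass, although Uty had stood at 59.8 CPM in Y-Scr. Eif2s3x rose by only 0.24 ± 0.07 beside the loss of Eif2s3y, at 129 CPM in Y-Scr. Usp9x and Uba1 rose although Usp9y and Uba1y had stood at only 0.269 and 0.531 CPM in Y-Scr. Zfx (-0.10 ± 0.08) cannot speak to this, since Zfy1 held 4 counts and Zfy2 0 in Y-Scr. The partner count depends on single libraries: without Y-Scr 2, Y-KO 1 or Y-KO 2 it was 3, and without Y-KO 3 it was 2.

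The 6 samples make 10 splits into 3 and 3, too few for a share under 0.05. In the real split, 2667 genes were higher and 2966 lower, with 175 and 561 at least 2-fold, and the highest counts of the other splits were 0, 0, 0 and 0, so 1 split of 10 reached each real count. For lists at the preset correlation the real split gave 4 higher and 10 lower and the highest others 9 and 9. Counted in either orientation of a split, as many lists were higher in 8 of the 10 splits, and as many lower in 1. Every other split mixes both groups on each side. The group difference then widens the spread within its sides, and part of it stays between them. Neither the gene counts nor the list counts of these splits therefore show what chance alone would give.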
